A study of Mus musculus with 76 samples.

How the data were processed

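The series holds bulk RNA sequencing of mouse thymus, lymph node and cultures titled Tregdiff. Per the labels it used the SMARTseq v4 low input kit, which copies full-length RNA from small inputs. It compares SOD1-G93A mice with wild-type mice. Sorted cTEC, mTEC, Treg and CD4 cells, iLN and cultures were deposited as counts per gene. The authors made these from their reads, and they were used as deposited. Whole thymus was deposited as TPM, a value the authors scaled by gene length and library so that it keeps no depth. The genome build mm10 and the tool DESeq2 are named, without a role, per the submitters' processing notes. The aligner, the counting tool and the handling of strand are not given in the sources used here. All tables have 55487 gene IDs, of which 55094 matched GENCODE vM21, the annotation of mm10 used here for symbols and positions.

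Libraries were grouped by genotype, population or tissue, day and culture time as the labels give them, and each table was analysed on its own. Total counts ran from 15135 to 36919936 per library. The fit of a population took all its libraries, so that 4 groups (or 6 in the cultures) share 1 estimate of the spread, and iLN and whole thymus were fitted alone. Contrasts gave the genotype difference on each day or time, the change with age or activation as the mean of both genotypes, and the interaction. The main test on counts was edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr by group, a dispersion per gene (estimateDisp) and glmQLFit with the legacy option followed by glmQLFTest, called at a Benjamini-Hochberg adjusted p under 0.05. The design, fixed before the data were examined, did not state the dispersion setting. The dispersion per gene was chosen on simulated counts after results with the edgeR default of a shared one had been seen. On simulated counts drawn from a model with a dispersion per gene, which favours this choice, it made 3021 true and 169 false calls (5.30% false), and the shared one 3576 true and 797 false (18.2%). Those simulations changed 200 genes per draw by 2 or 4 fold in 4 draws, and they were run after the first fits of the real counts.

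The design had foreseen counts for whole thymus too, and since the table holds TPM, limma 3.58.1 with a mean-variance trend was run on log2(TPM + 1) for genes with a mean of at least 1 TPM. A fold change on that scale understates the change of low genes.

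Levels in CPM use the total counts of each library over the genes that passed the filter, times its TMM factor. Genes at 0 in all libraries of a group were given as levels, without a fold. In list medians such genes were also set at a bound of 3 counts over the group. Gene lists, 31 sets of cell type markers and pathways, were fixed before the data were examined, as were the contrasts, the naming rule and most alternatives. They were tested with camera of limma on log2 CPM with a prior count of 2, a preset correlation of 0.01 and lists of 3 or more tested members, adjusted over the lists of a comparison. Camera with the correlation estimated for each list, and the rotation test fry, were the alternatives. The genes named were Sod1, up to 10 genes per direction with the smallest adjusted p under 0.05 and a mean of at least 5 CPM, with every library of 1 group on the same side of the other (dropped for averaged contrasts and interactions), and up to 4 members of each list described with the smallest p. Predicted or unnamed genes and immunoglobulin or T cell receptor segments were left out of the rule, and where fewer than 5 genes passed all those with a symbol were named. Some genes that met the rule are not reported here.

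Alternatives fixed in advance were DESeq2 1.42.0, median-of-ratios scaling, limma voom with sample quality weights, no filter on low counts, fits of the 2 groups alone, the replicate number as a block and each library left out in turn. Added after the data were seen were a shared dispersion, fits without libraries under 3e+05 counts or 8000 genes (8 libraries, among them iLN SOD1 2 and WT 2, cTEC d120 SOD1 3 and mTEC d30 SOD1 1), fits of iLN and cultures without rRNA-like and pile-up loci, the set of d120 libraries (numbers 1 to 3 or 4 to 6 in the column names) as a covariate, pseudocounts of 0.1 and 5 TPM, array weights for whole thymus in place of voom, T20 against T2 and list tests with each library left out or with the set of d120 libraries as a covariate. Transcripts of called loci were aligned to Sod1 with BLAST+ 2.17.0 at an E value under 0.001, with seqkit 2.13.0 for sequence handling, and data.table version 1.17.8, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 made the tables and plots.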

Results

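The thymus was profiled by bulk RNA sequencing in SOD1-G93A mice, a model of amyotrophic lateral sclerosis (ALS) that carries a mutant human SOD1 transgene, for superoxide dismutase 1, and in wild-type (WT) mice. The 76 libraries fell into 26 groups of 3 libraries, except for 2 groups of 2 (WT cortical thymic epithelial cells and WT CD4 cells, both of d30). Cortical thymic epithelial cells (cTEC), medullary thymic epithelial cells (mTEC), regulatory T cells (Treg) and CD4 T cells were sorted from the thymus at d30 and d120, giving 46 libraries. Whole thymus and inguinal lymph node (iLN) of d120 gave 6 libraries each. Cultures titled Tregdiff gave 18 libraries, without activation (T0) and at activation labelled T2 and T20, with no unit given. Total counts per library ran from 63887 to 894958 in iLN, 1269529 to 16776303 in cTEC, 15135 to 36919936 in mTEC, 1944589 to 34151147 in sorted Treg cells, 837050 to 14047347 in CD4 cells and 171619 to 19699330 in the cultures. Whole thymus was given in TPM, which scales each library to the same total and keeps no depth, with 20778 to 21693 genes above 0. Levels are given as mean ± SD in CPM, the counts scaled to library totals with TMM factors, and changes as log2 fold changes ± SE. Every p is adjusted unless called unadjusted.

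Markers were read first in the sorted populations. Psmb11, the thymoproteasome subunit of cTEC, stood at 798 ± 584 CPM in WT cTEC of d30 and 246 ± 74.7 CPM in those of d120 (n = 2 and 3). Aire, the regulator of tissue antigen expression in mTEC, stood at 989.9 ± 65.2 CPM in WT mTEC of d30 and 1243 ± 717 CPM at d120 (n = 3 each). Foxp3, the lineage factor of Treg cells, stood at 42.6 ± 7.18 CPM and 149 ± 96.9 CPM in the same days' WT Treg libraries (n = 3 each). The libraries labelled CD4 held 132 ± 82.4 CPM of Cd4 and 203 ± 54.6 CPM of Cd8a at d120 in WT (n = 3). On the log2(CPM + 1) scale double-positive thymocyte markers lay above the Treg signature in each of the 4 Treg groups, with highest group means of 7.73 and 5.72, and the Treg signature had group means of 4.55 to 4.70 in the 4 CD4 groups. Markers of other cells were also counted. Ptprc, the leukocyte antigen CD45, was at 301 ± 217 CPM in WT cTEC of d30 and 57.4 ± 25.3 CPM at d120, while the epithelial adhesion gene Epcam was at 333 ± 3.49 and 1369 ± 173 CPM. Cd79a, part of the B cell receptor, was at 19.9 ± 5.16 CPM in WT Treg libraries of d30 and 119.95 ± 65.8 CPM at d120.

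**Figure D1:**
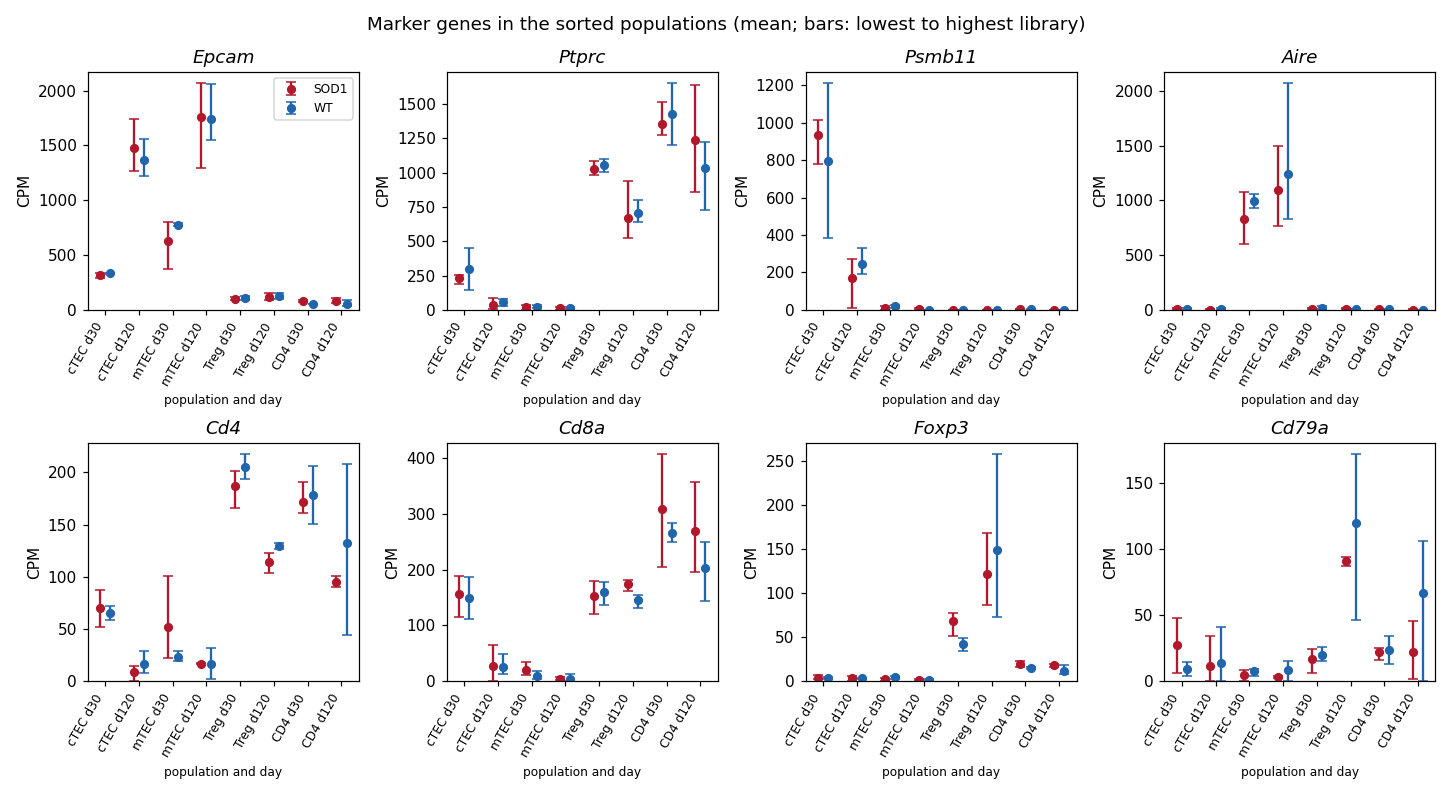
Marker levels in the sorted populations, in CPM on linear axes from 0 (vertical) by population and day (horizontal), a panel for each gene, red for SOD1 and blue for WT, with the mean of each group as a point and its lowest to highest library as the bar. Psmb11 in WT cTEC averages 798 CPM at d30 and 246 CPM at d120.

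The genotype was read first from Sod1, which encodes the enzyme that clears superoxide (chromosome 16, 90220754 to 90226329, plus strand, mm10 annotation). In whole thymus it stood at 4148 ± 616 TPM in SOD1 and 413 ± 30.3 TPM in WT mice (n = 3 each). In iLN the levels were 839 ± 213 and 126 ± 31.9 CPM. In the sorted cells of d30 Sod1 was at 542 ± 129 against 74.8 ± 5.15 CPM in cTEC, 222 ± 163 against 33.1 ± 2.06 in mTEC, 500.5 ± 139 against 48.5 ± 5.15 in Treg and 676 ± 296 against 43.4 ± 18.6 in CD4 cells. At d120 the pairs were 496 ± 159.5 and 83.1 ± 28.3 in cTEC, 314 ± 106 and 37.5 ± 21.3 in mTEC, 626 ± 306 and 66.4 ± 18.1 in Treg, and 681 ± 254 and 121 ± 79.9 in CD4 cells. The cultures held 3318 ± 325 against 253 ± 143 CPM at T0, 3310.3 ± 2021 against 330.1 ± 56.1 at T2 and 3331 ± 275 against 326 ± 36.5 at T20. Every SOD1 library lay above every WT library of its set in 12 of the 13 sets of tissue, population, day or culture time. The exception was mTEC of d30, where the library SOD1 1 had 15135 counts in all. Gm8566, a processed pseudogene on chromosome 6 (67205619 to 67206083, plus strand) that aligns to a Sod1 transcript over 465 bases at 97.8% identity, separated the genotypes in 13 of 13 sets. It is named here after its values were seen. In CPM it ran from 47.5 to 3990.4 in the 36 SOD1 libraries. The 34 WT libraries, 12 of them at 0, held at most 17.8 CPM except culture T0 WT 2 at 127. Its Sod1 of 417 CPM was the highest of these. Reads of the human transgene, mouse Sod1 and Gm8566 cannot be told apart here. So each level is uncertain, and a Sod1 change is one of its assigned counts.

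**Figure D2:**
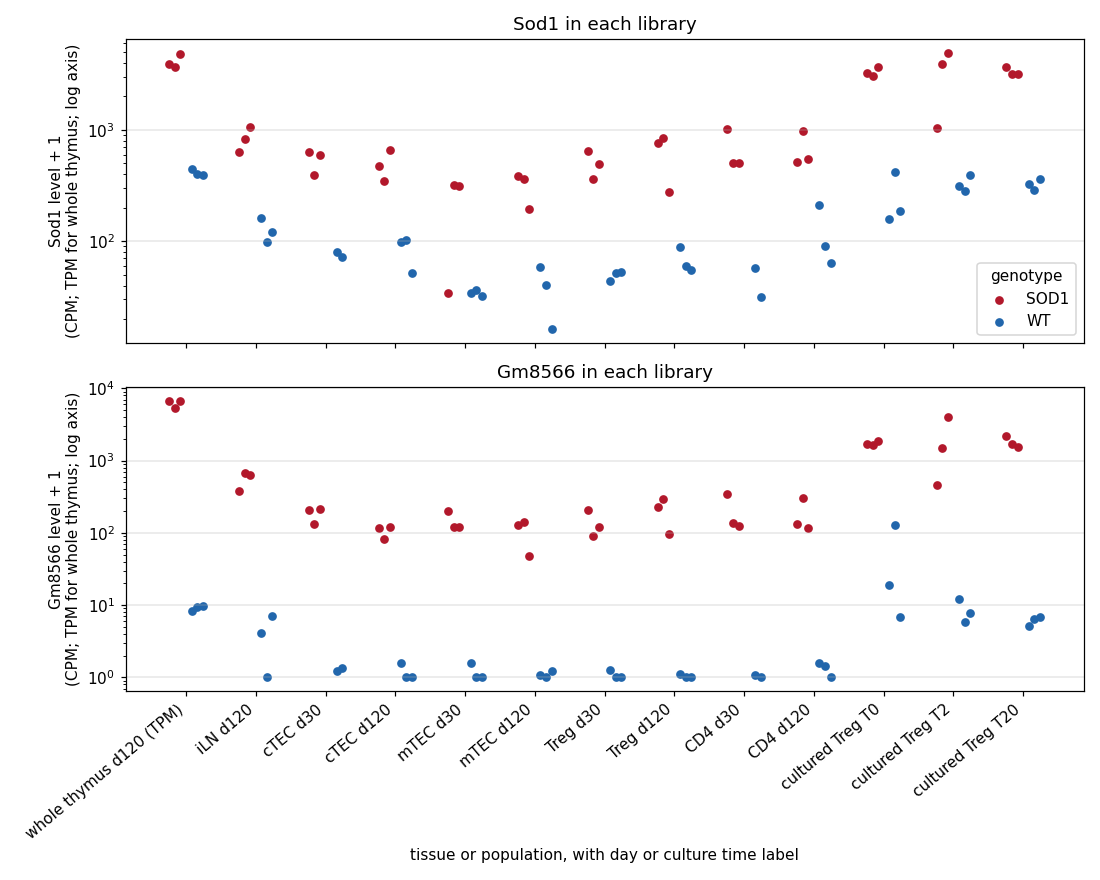
Sod1 (upper panel) and Gm8566 (lower panel) by tissue or population (horizontal axis), each point 1 library, as the level plus 1 on a log axis (vertical), in CPM or, for whole thymus, TPM, red for SOD1 and blue for WT. In CPM, Gm8566 was 47.5 to 3990.4 in SOD1 and at most 17.8 in WT, except 127 in culture T0 WT 2.

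Whole thymus of d120 was compared between genotypes. Beside Sod1 (log2 fold change 3.32 ± 0.12, limma adjusted p = 6.44e-05), SOD1 thymus held more Mtmr7, a phosphoinositide phosphatase, at 11.6 ± 1.59 against 1.32 ± 0.228 TPM (n = 3 each, limma adjusted p = 0.00804). Snora81, a small nucleolar RNA, was at 287 to 414 TPM in the SOD1 libraries and listed at 0 in all WT ones. Of 14437 genes tested on log2(TPM + 1), 12 passed, 10 higher and 2 lower in SOD1. The other genes lay outside the naming rule and were chosen after their values were seen. Gm8566 stood at 6213 ± 789 against 8.17 ± 0.763 TPM. Gm47295, Gm15324, Gm22567, 9530014B07Rik, Gm17917 and Gm8238 were listed at 0 in every WT library, with SOD1 libraries at 288 to 681, 44.9 to 64.5, 31.2 to 56.7, 15.1 to 17.05, 8.62 to 13.1 and 12.5 to 26.5 TPM. Gm6741 and the T cell receptor segment Trav11 were listed at 0 in every SOD1 library, with WT libraries at 6.11 to 8.61 and 10.2 to 45.3 TPM. Mtmr7 lost its call without SOD1 2 or SOD1 3 (adjusted p up to 0.0876) and without the filter on low values. Trav11 lost its call without SOD1 1, SOD1 2, SOD1 3 or WT 2 (adjusted p up to 0.265), without the filter and with a pseudocount of 5 TPM, and Gm6741 without WT 3 (adjusted p = 0.0530).

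No cell cycle gene passed the test in whole thymus. Among S phase genes, 0 rose, 0 fell and 21 did not pass (0 and 0 adjusted over the list alone), and 1 of 21 had a positive fold change. The list had a median of -0.20 (camera adjusted p = 6.22e-08, p = 0.726 with an estimated correlation). Its members with the smallest p were Uhrf1, which keeps DNA methylation through replication (-0.31 ± 0.08), and the helicase subunits Mcm5 (-0.29 ± 0.08) and Mcm2 (-0.28 ± 0.10). G2/M phase genes had a median of -0.20 (camera adjusted p = 5.41e-06, p = 0.930 with an estimated correlation), with Ccnb1, the mitotic cyclin B1, at -0.47 ± 0.10. That camera call was lost without SOD1 1 (adjusted p = 0.359). None of the 22 G2/M genes passed (0 and 0 adjusted over the list alone). Mitochondrially encoded transcripts had a median of -0.24 (camera adjusted p = 1.39e-04, p = 0.930 with an estimated correlation), a call lost without SOD1 2 (p = 0.0524).

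In iLN of d120, counts on Sod1 rose by 2.68 ± 0.35, and Gm8566 stood at 560.2 ± 164 against 3.02 ± 2.99 CPM. Gm10163 had no count in the SOD1 libraries and 127 ± 45.1 CPM in WT (n = 3 each, both predicted genes named after their values were seen). These 3 of 5226 genes tested passed, with adjusted p of 7.91e-04 to 0.0289 (edgeR quasi-likelihood test, Benjamini-Hochberg). Lyz2, a lysozyme of macrophages, was at -1.12 ± 0.33 and the lymphoid chemokine Ccl21a at -0.93 ± 0.36. Neither passed (adjusted p = 0.968 each). Myeloid and dendritic cell markers had a median of -0.92 (camera adjusted p = 0.00817, p = 0.557 with an estimated correlation). Of those 3 members none passed over all genes, and 1 was lower adjusted over the list alone. The 6 mTEC markers tested had a median of -0.75 (camera adjusted p = 0.00710, p = 0.495 with an estimated correlation), with 0 rising and 0 falling (0 and 0 adjusted over the list alone). Both list calls were lost without SOD1 1 or WT 3 (adjusted p up to 0.0738). Without SOD1 1, SOD1 3, WT 1, WT 2 or WT 3, 1 gene was called. Gm10163 lost its call in each fit (adjusted p up to 0.185), and Sod1 without any 1 library (adjusted p up to 0.352). Sod1 and Gm10163 lost theirs without the libraries of low depth (adjusted p = 0.361 and 0.0634), and Gm8566 and Gm10163 with limma voom (adjusted p = 0.429 and 0.772).

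The sorted populations asked in which thymic cells SOD1 and WT mice differ at a younger and an older age. In cTEC, Gm8566 was the 1 gene called on either day, at 182 ± 44.8 against 0.280 ± 0.0916 CPM at d30 (n = 3 and 2) and 105 ± 21.2 against 0.192 ± 0.332 CPM at d120 (n = 3 each). Sod1 had a log2 fold change of 2.86 ± 0.57 at d30 and 2.58 ± 0.48 at d120 and did not pass (adjusted p = 1 and 0.410, edgeR quasi-likelihood test, Benjamini-Hochberg). At d30, genes of 14620 tested with an unadjusted p under 0.05 numbered 47, and at d120 1327. With no difference a share of 0.05 would be due, and the d30 count lies far under it. Both days share 1 estimate of the spread, so the 2 numbers do not measure a change with age. DESeq2 called 5 and 208 genes, and limma voom 3 and 0. At d120 Gm8566 lost its call with limma voom (adjusted p = 0.339) and in the fit of the 2 groups alone (adjusted p = 0.978). At d30 the 9 tissue-restricted antigens of mTEC had a median of 1.36 (camera adjusted p = 1.07e-06, p = 0.0382 with an estimated correlation), among them the apolipoprotein gene Apoa4 at 1.62 ± 1.71. The 23 TCR-induced immediate early genes had a median of -0.43 (camera adjusted p = 5.46e-09, p = 0.0382 with an estimated correlation), with the NF-kappaB inhibitor Nfkbia at -0.45 ± 0.36 and the AP-1 subunit Junb at -0.43 ± 0.39. In both lists 0 rose and 0 fell (0 and 0 adjusted over the list alone). Without WT 3 Junb was at 0.21, the opposite sign. Both calls were lost without WT 3 (adjusted p = 0.984 and 0.237). With an estimated correlation each was lost in 4 of the 5 fits with 1 library left out (p up to 0.988 and 0.744). In the same comparison the cTEC markers themselves had a median of 0.23 and those of other cells 0.19 for mTEC, 0.54 for B cells, 0.21 for fibroblasts, 0.30 for adipocytes and -0.42 for erythroid cells and platelets (camera adjusted p = 4.64e-07 to 0.0480, p = 0.169 to 0.378 with an estimated correlation), with 0 members of these lists rising or falling over all genes (0 and 0 adjusted over the list alone). Each call but that of cTEC markers was lost without 1 or more of SOD1 1, SOD1 2, SOD1 3, WT 2 or WT 3 (adjusted p up to 0.911), and cTEC markers were called in the other direction without WT 2. Gm8566 lost its d30 call without any 1 of the 5 libraries, with 0 genes called each time. At d120 leaving out 1 library gave 0 without SOD1 1, WT 1 or WT 2 and 2 without SOD1 3, and the gene called without WT 3 was not Gm8566.

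In mTEC, Gm8566 was again the 1 gene called on each day, at 147 ± 47.0 against 0.194 ± 0.336 CPM at d30 and 105 ± 50.5 against 0.105 ± 0.122 CPM at d120 (n = 3 each). Sod1 stood at 2.96 ± 0.55 and 3.06 ± 0.54 and did not pass (edgeR quasi-likelihood adjusted p = 0.802 and 0.255 after Benjamini-Hochberg). At d30 all 18 genes of cholesterol synthesis had a positive fold change, with Cyp51, a sterol demethylase, at 1.23 ± 0.52 and the HMG-CoA synthase gene Hmgcs1 at 0.91 ± 0.39. None of them passed (0 and 0 adjusted over the list alone), and the list had a median of 0.40 (camera adjusted p = 3.42e-04, p = 0.951 with an estimated correlation). The rotation test fry gave that list the opposite direction (adjusted p = 0.919). Mitochondrially encoded transcripts of d30 had a median of -0.54 (camera adjusted p = 8.90e-04, p = 0.951 with an estimated correlation), lost without SOD1 2 (p = 0.0614). The unadjusted p was under 0.05 for 68 of 18919 genes at d30 and for 1546 at d120, with 4 and 87 called by DESeq2 and 2 and 0 by limma voom. Leaving out 1 library of d120 gave 79 without WT 1 and 12 without WT 3.

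In sorted Treg cells counts on Sod1 rose by 3.37 ± 0.38 at d30 and 3.23 ± 0.37 at d120, and Gm8566 from 0.0923 ± 0.1599 to 139 ± 60.05 CPM and from 0.0325 ± 0.0563 to 204 ± 99.5 CPM (n = 3 each). These were the 2 genes called on each day, with an adjusted p of 0.00591 and 0.00844 for Sod1 (edgeR quasi-likelihood test, Benjamini-Hochberg). No member of a fixed list passed on either day, nor did any adjusted over the list alone except where given. At d30 the Treg signature had a median of 0.30 (camera adjusted p = 1.58e-04, p = 0.733 with an estimated correlation), with Foxp3 at 0.67 ± 0.39. Genes of MHC class II presentation had a median of 0.35 (camera adjusted p = 2.72e-05, p = 0.733 with an estimated correlation), with the lysosomal protease genes Lgmn at 1.05 ± 0.28 and Ctss at 0.52 ± 0.22 (1 higher and 0 lower adjusted over the list alone). Both calls were lost without SOD1 2 (adjusted p = 0.0730 and 0.159). Type I interferon response genes had a median of 0.24 (camera adjusted p = 3.59e-04, p = 0.406 with an estimated correlation), with Ifi27l2a at 0.67 ± 0.37. At d120 the Treg signature had a median of -0.34 (camera adjusted p = 0.0143, p = 0.695 with an estimated correlation), lost without SOD1 1, SOD1 2 or WT 1 (adjusted p up to 0.755). The d120 class II list had a median of -0.45 (camera adjusted p = 1.34e-04, p = 0.601 with an estimated correlation), with its activator Ciita at -1.44 ± 0.37 and H2-Ob at -1.13 ± 0.35 (0 higher and 2 lower adjusted over the list alone). Beside it mTEC markers, of another cell type, had a median of -0.62 (camera adjusted p = 0.0143, p = 0.601 with an estimated correlation), lost without SOD1 1 or WT 3 (p up to 0.0638). Mitochondrially encoded transcripts had a median of -0.50 (camera adjusted p = 3.22e-04, p = 0.623 with an estimated correlation), lost without SOD1 2 or WT 3 (p up to 0.211), and nuclear genes of oxidative phosphorylation a median of 0.17 (camera adjusted p = 0.0160, p = 0.812 with an estimated correlation), lost without SOD1 1, SOD1 2 or WT 3 (p up to 0.651).

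S phase genes of SOD1 Treg cells at d120 had a median of 0.30 (camera adjusted p = 1.59e-04, p = 0.601 with an estimated correlation), with the cell cycle regulator E2f1 at 0.77 ± 0.16 and Mcm2 at 0.52 ± 0.12 (2 higher and 0 lower adjusted over the list alone). Inflammatory cytokines and chemokines had a median of -0.48 (camera adjusted p = 3.28e-04, p = 0.580 with an estimated correlation), with Cxcl2, a neutrophil attractant, at -1.52 ± 0.48 and Tnf at -1.64 ± 0.53 (0 higher and 1 lower adjusted over the list alone). B cell markers lay on the same side at d120, with a median of -0.54 (camera adjusted p = 0.0143, p = 0.623 with an estimated correlation), a call lost without SOD1 1, WT 1 or WT 2 (adjusted p up to 0.348). Sod1 lost its call at d30 without any 1 of the WT libraries (adjusted p up to 0.0882) and at d120 without WT 2 (adjusted p = 0.136), and in a fit of the 2 groups of d120 alone Gm8566 was the 1 gene called. Leaving out 1 library gave 1 without WT 2 or WT 3 at d30 and 4 without WT 1, 1 without WT 2 and 7 without WT 3 at d120. By the numbers in their column names, 2 of the 3 SOD1 libraries of d120 belong to a set 1 to 3 and 2 of the 3 WT libraries to a set 4 to 6, and this split of the libraries gave 683 genes. Between the sets the medians were -0.42 for class II, 0.23 for S phase, -0.91 for inflammatory genes, -1.48 for mitochondrially encoded transcripts (11 of 13 passing) and 0.46 for oxidative phosphorylation (9 of 26 passing), on the same side as between genotypes, and 0.28 for the Treg signature. With the set as a covariate, chosen after the data were seen, the genotype medians for class II, S phase, inflammatory and Treg signature genes were -0.38, 0.21, -0.17 and -0.32, with a camera adjusted p of 0.0215, 0.00262, 0.0283 and 0.0215 (adjusted p = 0.772 to 0.873 with an estimated correlation), and the calls of B cell markers, mTEC markers, mitochondrially encoded transcripts and oxidative phosphorylation were lost (adjusted p = 0.0615, 0.113, 0.155 and 0.795). DESeq2 called 7 genes at d30 and 49 at d120, and limma voom 2 and 1, with Sod1 but not Gm8566 (adjusted p = 0.0801 and 0.282) passing.

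In CD4 cells Gm8566 was the 1 gene called, at 201 ± 123 against 0.0410 ± 0.0580 CPM at d30 (n = 3 and 2) and 183 ± 103 against 0.345 ± 0.308 CPM at d120 (n = 3 each). Sod1 stood at 3.95 ± 0.64 and 2.48 ± 0.51 and did not pass (edgeR quasi-likelihood adjusted p = 0.176 and 0.538 after Benjamini-Hochberg). At d120 all 12 T helper lineage genes had a negative fold change, among them the follicular homing receptor Cxcr5 (-2.79 ± 1.05) and the transcriptional repressor Bcl6 (-1.35 ± 0.60). None passed (0 and 0 adjusted over the list alone), and the list had a median of -0.85 (camera adjusted p = 0.00811, p = 0.720 with an estimated correlation). That call was lost without SOD1 2 or WT 2 (adjusted p up to 0.191). Myeloid and dendritic cell markers lay on the same side, with a median of -1.56 (camera adjusted p = 0.00889, p = 0.745 with an estimated correlation), lost without SOD1 1, SOD1 2, WT 1 or WT 2 (p up to 0.521). So did genes of MHC class II presentation, with a median of -0.88 (camera adjusted p = 0.00889, p = 0.821 with an estimated correlation), lost without SOD1 1, SOD1 2, WT 1 or WT 2 (p up to 0.304), and mitochondrially encoded transcripts, with a median of -0.45 (camera adjusted p = 0.00811, p = 0.745 with an estimated correlation), lost without SOD1 1 or WT 2 (p up to 0.373). The unadjusted p was under 0.05 for 35 of 12479 genes at d30 and 776 at d120, while DESeq2 called 5 and 40 and limma voom 4 and 0. Leaving out 1 library gave 2 without SOD1 2 and 0 without WT 2 at d30, where Gm8566 lost its call without WT 2 (adjusted p = 0.111), and 2 without SOD1 3, 13 without WT 1 and 3 without WT 3 at d120. The d120 libraries fall into the same sets of column numbers as in Treg cells, and that split gave 293 genes, with a median of -0.57 for T helper genes and -0.37 for mitochondrially encoded transcripts and negative ones for myeloid markers and class II, on the same side as between genotypes. With the set as a covariate the genotype medians of T helper and myeloid lists were -0.62 and -1.58 (camera adjusted p = 0.0234 and 0.0454, p = 0.663 and 0.670 with an estimated correlation). Mitochondrially encoded transcripts stood at -0.41 (camera adjusted p = 0.0454, p = 0.726 with an estimated correlation), and the call of class II was lost (adjusted p = 0.0828).

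Whether the genotype difference itself differed between d30 and d120 was tested as an interaction in each population. The edgeR quasi-likelihood test called 0 genes in each of cTEC, mTEC, Treg and CD4 cells, with 550, 783, 540 and 277 at an unadjusted p under 0.05, 25, 10, 6 and 3 by DESeq2 and 0 by limma voom in each. Genes of MHC class II presentation in Treg cells had the interaction call with the smallest camera p. All 12 had a lower genotype effect at d120 than at d30, with a median of -0.81 (camera adjusted p = 2.67e-10, p = 0.362 with an estimated correlation), and 0 of them rose or fell (0 and 0 adjusted over the list alone). S phase genes in Treg cells had a median of 0.33 (camera adjusted p = 1.23e-05, p = 0.433 with an estimated correlation), with 0 rising and 0 falling (2 and 0 adjusted over the list alone). mTEC markers had a median of -0.93 (camera adjusted p = 6.75e-04, p = 0.362 with an estimated correlation), with 0 rising and 0 falling (0 and 0 adjusted over the list alone). These 3 lists kept their camera calls with each library left out. Mitochondrially encoded transcripts had a median of -0.52 (camera adjusted p = 0.00348, p = 0.668 with an estimated correlation), lost without d120 SOD1 1, d120 SOD1 2 or d120 WT 3 (p up to 0.432). With the set of d120 libraries as a covariate the medians of class II, S phase and mTEC marker lists were -0.73, 0.32 and -0.92 (camera adjusted p = 3.98e-06, 1.26e-04 and 0.0148, p = 0.622 each with an estimated correlation), and the mitochondrial call was lost (adjusted p = 0.414). With single libraries left out, 1 gene passed in cTEC without d120 WT 3, 5 in mTEC without d120 WT 3, 1 in Treg cells without d120 WT 3 and 1 without d30 SOD1 2, and in CD4 cells 2 without d120 WT 3 and 1 without d30 SOD1 2.

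Age was compared over both genotypes in each population, and library names differ between the days, so age and library batch cannot be told apart. In cTEC, the genes that rose by d120 included F3, the tissue factor that starts coagulation (4.38 ± 0.37), the annexin gene Anxa1 (3.64 ± 0.33), the small heat shock protein gene Hspb1 (3.88 ± 0.38), the AP-1 subunit Fosl1 (5.36 ± 0.62) and the small GTPase Rrad (3.32 ± 0.32; n = 6 at d120 and 5 at d30). Among the genes that fell were Ccr7, the receptor that guides lymphocytes and dendritic cells (-7.23 ± 1.02), the actin bundler Fscn1 (-6.01 ± 0.85), Lsp1 (-4.68 ± 0.67), Tmem123 (-3.71 ± 0.48) and Tcf7, a transcription factor of the T lineage (-2.69 ± 0.38). In all 677 genes passed, 236 higher and 441 lower at d120 of 14620 tested, and the adjusted p of the genes with a fold change above ran from 2.66e-04 to 0.00272 (edgeR quasi-likelihood test, Benjamini-Hochberg).

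Lists of stress genes were among those called in cTEC by age. Among genes of the heat shock and unfolded protein response, 9 of 23 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 9.01e-14, p = 0.0109 with an estimated correlation). Examples were the chaperone cofactor Dnajb1 (1.48 ± 0.26) and the stress factors Atf3 (2.02 ± 0.27) and Atf4 (1.97 ± 0.35). Among glucocorticoid response genes, 5 of 15 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.24 (camera adjusted p = 2.27e-07, p = 0.0109 with an estimated correlation). The kinase gene Sgk1 (3.38 ± 0.41), the phosphatase gene Dusp1 (1.65 ± 0.28) and the metallothionein Mt2 (3.67 ± 0.60) were among them. Among immediate early genes, 7 of 23 rose and 0 fell (11 and 3 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 2.27e-07, p = 0.0539 with an estimated correlation). Fos (1.53 ± 0.20), Jun (1.42 ± 0.23) and Nfkbia (1.91 ± 0.26) rose. Among mitochondrially encoded transcripts, 11 of 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.90 (camera adjusted p = 2.83e-25, p = 0.0699 with an estimated correlation). Cytochrome b, mt-Cytb, was at 2.04 ± 0.30.

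Markers of blood cells had negative medians in the cTEC libraries of d120. Among myeloid and dendritic cell markers, 0 of 16 rose and 5 fell (0 and 11 adjusted over the list alone), with a median of -3.79 (camera adjusted p = 3.41e-06, p = 0.315 with an estimated correlation). With members at 0 on 1 side set at their bound, that median was -3.56. The antigen presentation gene Cst3 was at -2.70 ± 0.53. Among double-positive thymocyte markers, 0 of 16 rose and 5 fell (0 and 9 adjusted over the list alone), with a median of -2.53 (camera adjusted p = 2.41e-04, p = 0.319 with an estimated correlation). Dntt, the polymerase of junctional diversity, was at -3.86 ± 0.73 and the CD3 subunit Cd3e at -3.35 ± 0.55. Among G2/M phase genes, 0 of 22 rose and 6 fell (0 and 19 adjusted over the list alone), with a median of -3.23 (camera adjusted p = 3.21e-10, p = 0.170 with an estimated correlation). Ube2c, which tags mitotic cyclins for destruction, was at -4.91 ± 0.93. Ptprc, counted in the same libraries, averaged 233 and 301 CPM in SOD1 and WT at d30 and 34.6 and 57.4 CPM at d120. The count of 677 depended on single libraries, with 1805 without d120 SOD1 3, 300 without d120 WT 1, 366 without d120 WT 3, 199 without d30 SOD1 1 (114 higher, 85 lower), 175 without d30 SOD1 2 (94 higher, 81 lower), 230 without d30 SOD1 3 (120 higher, 110 lower), 80 without d30 WT 2 (56 higher, 24 lower) and 220 without d30 WT 3.

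In mTEC of d120, Cldn4, a tight junction claudin of mTEC (2.69 ± 0.21), Fosl1 (4.07 ± 0.36), Hspb1 (2.38 ± 0.22), Atf4, the main factor of the integrated stress response (1.99 ± 0.19), the kinase Itpkc (2.95 ± 0.28) and Tnfrsf12a, the receptor of the cytokine TWEAK (4.16 ± 0.40), were higher than at d30 (n = 6 each). Cenpe, a motor of the kinetochore (-4.23 ± 0.63), the cell cycle inhibitor Cdkn1c (-1.89 ± 0.29), the mitochondrial channel Vdac1 (-1.66 ± 0.25) and the muscle genes Acta1 (-4.86 ± 0.67) and Myh11 (-1.37 ± 0.24) were lower. The test called 597 genes, 396 higher and 201 lower at d120 of 18919 tested. For the genes named, adjusted p ran from 6.59e-05 to 0.00625 (edgeR quasi-likelihood test, Benjamini-Hochberg). With single libraries left out the count was 391 without d120 SOD1 1, 1049 without d120 WT 1 (431 higher, 618 lower), 961 without d120 WT 3, 225 without d30 SOD1 2, 224 without d30 SOD1 3, 226 without d30 WT 1, 300 without d30 WT 2 and 266 without d30 WT 3.

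Lists of stress and signalling genes were called in mTEC by age with the preset correlation, and none of them with an estimated one. Among heat shock and unfolded protein response genes, 11 of 23 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.15 (camera adjusted p = 1.62e-17, p = 0.171 with an estimated correlation). Bag3, a cochaperone, was at 2.45 ± 0.30 and Atf3 at 2.50 ± 0.31. Among immediate early genes, 14 of 23 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.48 (camera adjusted p = 1.62e-17, p = 0.171 with an estimated correlation). Jund was at 1.72 ± 0.22, Ier3 at 2.14 ± 0.29 and Myc at 2.01 ± 0.28. Among p53 targets and apoptosis genes, 3 of 18 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 3.49e-06, p = 0.487 with an estimated correlation). Mdm2, which marks p53 for degradation, was at 1.58 ± 0.24 and Gadd45a at 1.06 ± 0.21. Among glucocorticoid response genes, 8 of 15 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 2.77e-05, p = 0.487 with an estimated correlation). Mt1 was at 2.36 ± 0.26 and the clock gene Per1 at 2.26 ± 0.34. Among mTEC markers, 4 of 19 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 6.71e-04, p = 0.630 with an estimated correlation). The keratin gene Krt14 (1.64 ± 0.31) and Ccl21a (1.81 ± 0.31) rose while Spib, a factor of late mTEC stages, fell (-1.24 ± 0.23).

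In sorted Treg cells of d120, Nfkb1, a subunit of NF-kappaB (1.85 ± 0.13), Ddit3, a stress-induced transcription factor (2.63 ± 0.17), Cables1 (4.39 ± 0.26), the interferon receptor subunit Ifnar2 (1.40 ± 0.10) and the potassium channel Kcnn4 (1.47 ± 0.11) rose (n = 6 each). Rag1, the recombinase of antigen receptor genes (-1.96 ± 0.14), Dntt (-1.86 ± 0.14), the DNA polymerase subunit Pola1 (-2.74 ± 0.17) and the adhesion protein Tln1 (-1.48 ± 0.11) fell. The comparison called 4433 genes, 2387 higher and 2046 lower at d120 of 14824 tested, and the genes named had adjusted p values of 4.22e-06 to 8.68e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg). Among G2/M phase genes, 0 of 22 rose and 15 fell (0 and 16 adjusted over the list alone), with a median of -0.96 (camera adjusted p = 1.89e-08, p = 0.549 with an estimated correlation). Top2a, which untangles chromosomes, was at -1.08 ± 0.16. Among double-positive thymocyte markers, 2 of 16 rose and 8 fell (3 and 9 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 4.59e-04, p = 0.549 with an estimated correlation). Among B cell markers (another cell type), 7 of 12 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 1.36 (camera adjusted p = 4.59e-04, p = 0.549 with an estimated correlation). Ebf1, a B lineage factor, was at 3.59 ± 0.47 and Cd79a at 2.53 ± 0.35.

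In CD4 cells of d120, Gzmb, the cytotoxic protease granzyme B (3.49 ± 0.30), Ctla2a (3.58 ± 0.37), the NK receptor Klrc1 (2.42 ± 0.27) and Ramp3 (2.84 ± 0.26) rose (n = 6 at d120 and 5 at d30). Mcm2 (-2.05 ± 0.25), Mcm3 (-1.71 ± 0.22), Fos (-2.43 ± 0.28) and the actin regulators Lcp1 (-2.06 ± 0.24) and Coro1a (-1.69 ± 0.21) fell. The test called 1321 genes, 582 higher and 739 lower at d120 of 12479 tested, with adjusted p values of 2.20e-04 to 0.00151 for the genes named (edgeR quasi-likelihood test, Benjamini-Hochberg). Among G2/M phase genes, 0 of 22 rose and 18 fell (0 and 20 adjusted over the list alone), with a median of -1.64 (camera adjusted p = 1.24e-12, p = 0.00826 with an estimated correlation). Among S phase genes, 0 of 21 rose and 12 fell (0 and 14 adjusted over the list alone), with a median of -1.30 (camera adjusted p = 4.12e-08, p = 0.0579 with an estimated correlation). Among mitochondrially encoded transcripts, 11 of 13 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.63 (camera adjusted p = 1.40e-13, p = 0.134 with an estimated correlation). The complex I gene mt-Nd6 was at 2.12 ± 0.24. Among genes of MHC class II presentation, 0 of 12 rose and 9 fell (0 and 11 adjusted over the list alone), with a median of -1.53 (camera adjusted p = 1.57e-05, p = 0.371 with an estimated correlation). H2-Ab1 was at -1.60 ± 0.40. Markers of other cells that hold class II lay on the same side. Among myeloid and dendritic cell markers, 0 of 15 rose and 4 fell (0 and 4 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 0.0165, p = 0.397 with an estimated correlation). That call was lost without d120 WT 3 or d30 WT 2 (p up to 0.0930). B cell markers had a median of -1.29 and were not called (camera adjusted p = 0.0814), with 0 rising and 2 falling (1 and 3 adjusted over the list alone). Leaving out 1 library gave 844 without d30 SOD1 1, 682 without d30 SOD1 2, 570 without d30 SOD1 3, 156 without d30 WT 2 and 274 without d30 WT 3.

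Helper and cytotoxic lists and markers of other cells were also called in CD4 cells by age. Among T helper lineage genes, 4 of 12 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 1.22 (camera adjusted p = 4.14e-04, p = 0.206 with an estimated correlation). Ifng, the cytokine of type 1 responses, was at 1.95 ± 0.47 and the lineage factors Maf and Gata3 at 2.81 ± 0.68 and 1.16 ± 0.31. Among CD8, NK and cytotoxic markers, 4 of 13 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.00314, p = 0.371 with an estimated correlation). Fasl, the death ligand, was at 2.83 ± 0.44. Among cTEC markers (another cell type), 0 of 12 rose and 4 fell (0 and 7 adjusted over the list alone), with a median of -2.12 (camera adjusted p = 0.00142, p = 0.316 with an estimated correlation). The keratin gene Krt8 was at -4.51 ± 1.12 and the chemokine Cxcl12 at -5.08 ± 1.39.

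**Figure D3:**
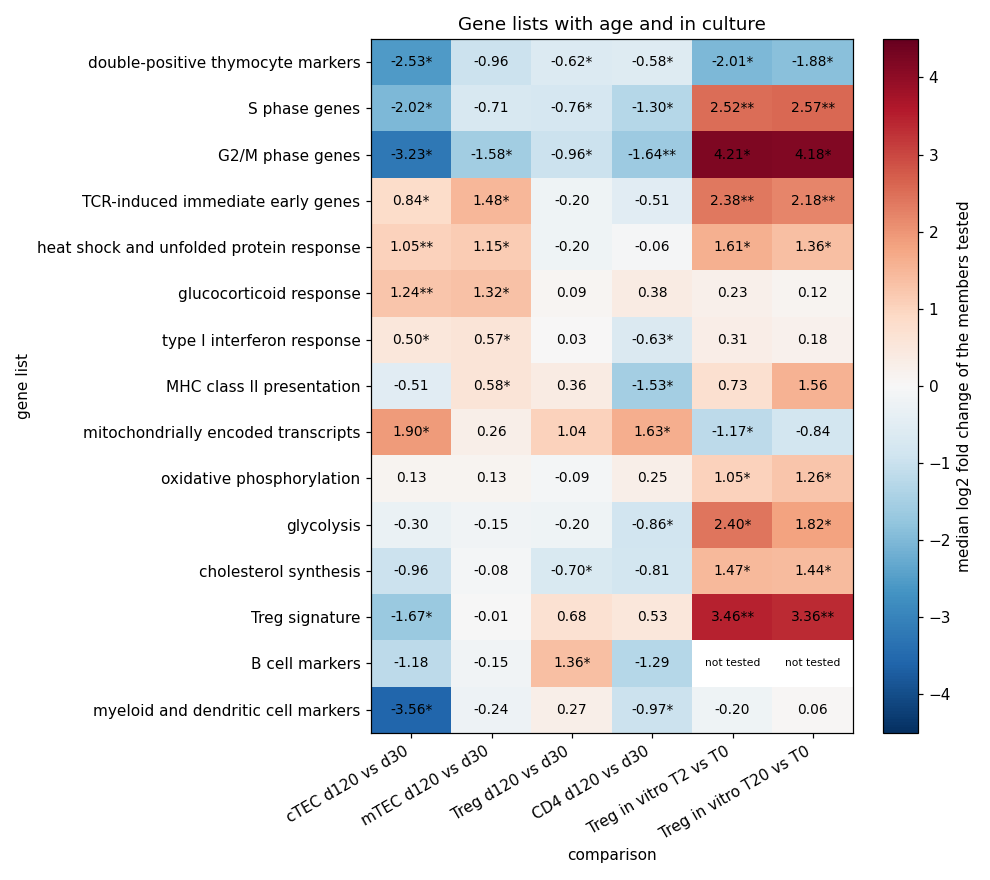
Median log2 fold change, as number and colour, of selected gene lists (vertical axis) in the age and culture time comparisons (horizontal axis), with genes at 0 on 1 side at their bound, blue for lower and red for higher. One star marks a camera adjusted p under 0.05 with the preset correlation and a second star one that held with an estimated correlation, as for G2/M phase genes in CD4 cells (-1.64).

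The cultures titled Tregdiff were compared between T0 and activation at T2 and T20. Whether their cells were Treg cells at T0 was not tested. At T2, Cdk1, the kinase that drives mitosis (4.58 ± 0.30), the mitotic kinase Aurkb (4.38 ± 0.30), the spindle motor Kif11 (4.48 ± 0.30), the midzone protein Prc1 (4.09 ± 0.28) and Tfdp1, the partner of E2F factors (3.32 ± 0.23), were higher than at T0 (n = 6 each). Dntt (-7.30 ± 0.40), the T cell factor Lef1 (-3.34 ± 0.23), the kinase Pdk1 (-3.77 ± 0.25) and the actin crosslinker Actn1 (-4.72 ± 0.32) were lower. At T20 against T0 Cdk1 was at 4.22 ± 0.30, Aurkb at 4.59 ± 0.31, Dntt at -6.23 ± 0.37 and Lef1 at -3.17 ± 0.23. Foxp3 averaged 14.4 and 8.23 CPM in SOD1 and WT at T0, 189.5 and 73.4 CPM at T2 and 156 and 104 CPM at T20. The test called 6850 genes at T2 (2802 higher, 4048 lower) and 6863 at T20 (2845 higher, 4018 lower) of 11787 tested. Adjusted p of the genes named ran from 2.16e-09 to 1.26e-08 at T2 (edgeR quasi-likelihood test, Benjamini-Hochberg). Both times were set against the same T0 libraries, so their changes are not independent.

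Activation and division genes moved as groups. Among Treg signature genes at T2, 23 of 25 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 3.46 (camera adjusted p = 1.99e-12, p = 0.0314 with an estimated correlation). Il2rb, a subunit of the interleukin 2 receptor, was at 4.38 ± 0.37, Ccr8 at 4.64 ± 0.40 and Capg at 3.75 ± 0.30. Among TCR-induced immediate early genes at T2, 21 of 22 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 2.38 (camera adjusted p = 1.21e-09, p = 0.0314 with an estimated correlation). The nuclear receptors Nr4a1 and Nr4a3 were at 4.71 ± 0.47 and 5.60 ± 0.52. Among S phase genes at T2, 17 of 21 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 2.52 (camera adjusted p = 1.99e-12, p = 0.0314 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 4.71 ± 0.38. Among G2/M phase genes at T2, 21 of 22 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 4.21 (camera adjusted p = 5.86e-16, p = 0.0530 with an estimated correlation). At T20 the medians of these 4 lists were 3.36, 2.18, 2.57 and 4.18. Their camera adjusted p at T20 was at most 3.29e-09, and p = 0.0369 for the first 3 and 0.0517 for the last with an estimated correlation. Members higher and lower at T20 numbered 23 and 2, 21 and 1, 19 and 0, and 21 and 0 (the same numbers adjusted over the list alone).

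Metabolic genes and markers of T cell stages were also called at T2. Among glycolysis genes, 15 of 17 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 2.40 (camera adjusted p = 2.21e-08, p = 0.256 with an estimated correlation). Ldha, lactate dehydrogenase, was at 3.07 ± 0.31. Among nuclear genes of oxidative phosphorylation, 20 of 26 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 1.01e-05, p = 0.328 with an estimated correlation). Cytochrome c, Cycs, was at 2.50 ± 0.33. Among mitochondrially encoded transcripts, 0 of 13 rose and 10 fell (0 and 10 adjusted over the list alone), with a median of -1.17 (camera adjusted p = 0.00786, p = 0.348 with an estimated correlation). Among double-positive thymocyte markers, 0 of 15 rose and 12 fell (0 and 12 adjusted over the list alone), with a median of -2.01 (camera adjusted p = 4.73e-04, p = 0.140 with an estimated correlation). The thymocyte signalling gene Themis was at -3.58 ± 0.36. Among T cell maturation and egress genes, 3 of 16 rose and 11 fell (3 and 11 adjusted over the list alone), with a median of -2.36 (camera adjusted p = 0.00417, p = 0.328 with an estimated correlation). The interleukin 7 receptor gene Il7r was at -4.86 ± 0.38 and Ccr9, which directs cells to gut and thymus, at -5.49 ± 0.53. Among T helper lineage genes, 11 of 14 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 3.16 (camera adjusted p = 4.00e-04, p = 0.181 with an estimated correlation). Tnf was at 4.30 ± 0.39 and the type 1 factor Tbx21 at 3.86 ± 0.48.

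**Figure D4:**
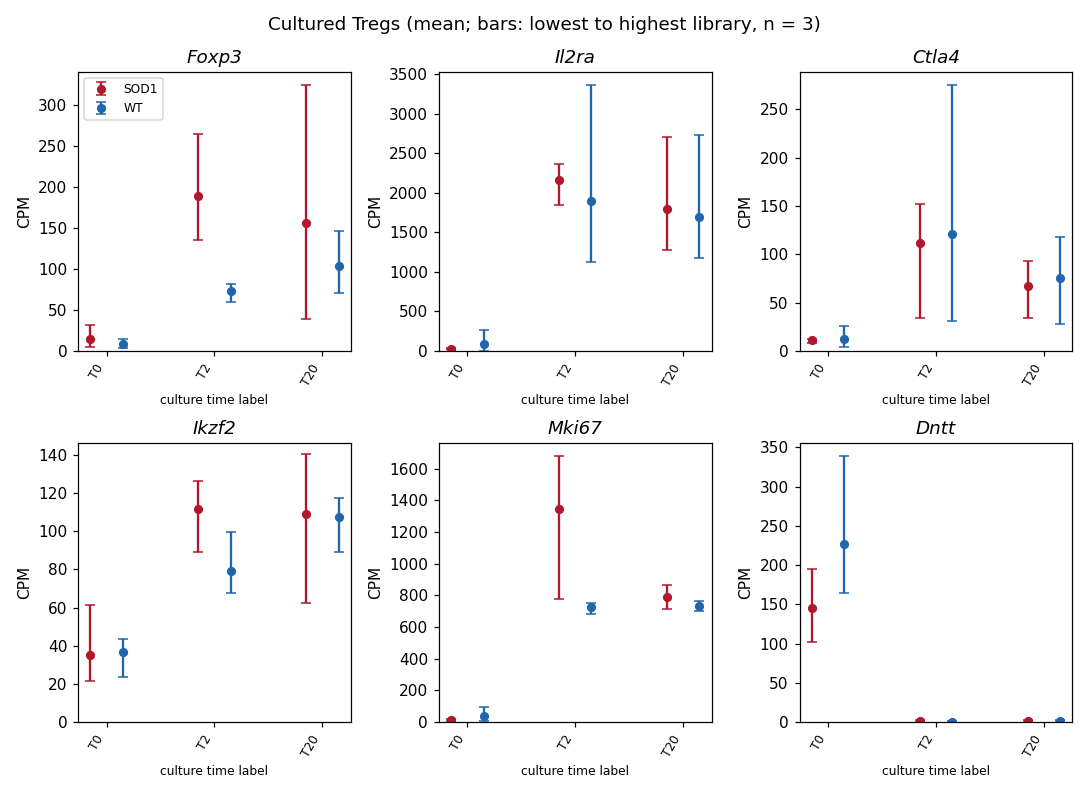
Levels of 6 genes in the cultures, in CPM on linear axes from 0 (vertical) by culture time (horizontal). Red is SOD1 and blue WT, points are means of 3 libraries and bars run from lowest to highest. Il2ra averages 90.2 CPM at T0 and 1900.1 CPM at T2 in WT.

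Between genotypes of the cultures, counts on Sod1 rose by 3.70 ± 0.49 at T0, 3.32 ± 0.48 at T2 and 3.35 ± 0.48 at T20 (n = 3 each). At T0 Zdhhc2, a palmitoyltransferase, was at 31.3 ± 18.9 against 1.37 ± 1.59 CPM. Shcbp1, a protein of dividing cells, was at 0.194 ± 0.336 against 5.35 ± 4.97 CPM. At T2 Prkrip1 was at 18.3 ± 7.19 against 85.0 ± 9.22 CPM and Ier3ip1, of the endoplasmic reticulum, at 62.4 ± 30.7 against 232 ± 51.1 CPM. Creb3l3, a membrane-bound transcription factor, was at 19.8 ± 17.3 against 0.0650 ± 0.113 CPM at T2 and 19.1 ± 7.78 against 0.0893 ± 0.155 at T20. At T20 the zinc finger gene Zfp870 was at 29.0 ± 5.28 against 1.53 ± 0.471 CPM and the photoreceptor gene Rd3 at 12.2 ± 4.27 against 0.0446 ± 0.0773. The test called 8 genes at T0, 11 at T2 and 11 at T20 of 11787 tested, with adjusted p of 1.54e-05 to 0.0364, 1.23e-05 to 0.0349 and 6.60e-05 to 0.0230 (edgeR quasi-likelihood test, Benjamini-Hochberg). Calls were lost with 1 library left out at T0 for Zdhhc2 (without SOD1 2, WT 1, WT 2 or WT 3) and Shcbp1 (without SOD1 1, SOD1 2, SOD1 3, WT 2 or WT 3), with adjusted p up to 0.512, at T2 for Sod1 (without WT 2 or WT 3), Creb3l3 (without WT 2 or WT 3), Prkrip1 (without SOD1 1, SOD1 3, WT 2 or WT 3) and Ier3ip1 (without SOD1 1, WT 1, WT 2 or WT 3), with adjusted p up to 0.307. They were lost at T20 for Zfp870 (without SOD1 1, WT 1 or WT 3) and Rd3 (without SOD1 1, SOD1 2, WT 1, WT 2 or WT 3), with adjusted p up to 0.456.

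Several of the culture genes are predicted loci, named after their values were seen. Gm15772 stood at 3.29 ± 0.862 against 179 ± 20.9 CPM at T0, 7.86 ± 8.44 against 286 ± 77.8 at T2 and 5.87 ± 3.10 against 218 ± 35.1 at T20. In all 4 sorted populations of d120, WT 2 lay under 5 CPM of Gm15772 and SOD1 2 and SOD1 3 over 20 CPM. Gm8566, Gm5949, Olfr1193 and 9530014B07Rik were called at all 3 times, Gm38292 at T2 and T20, Gm11942 at T2 and Gm8238 at T20. With 1 library left out, calls were lost at T0 for Gm8566 (without WT 1), Gm5949 (without SOD1 1 or WT 3), Olfr1193 (without any 1 of the 6 libraries) and 9530014B07Rik (without WT 2 or WT 3), with adjusted p up to 0.265. They were lost at T2 for Gm5949 (without WT 2 or WT 3), Olfr1193 (without WT 2 or WT 3), 9530014B07Rik (without WT 3), Gm38292 (without SOD1 2, WT 2 or WT 3) and Gm11942 (without SOD1 1 or WT 3), with adjusted p up to 0.307. They were lost at T20 for Olfr1193 (without SOD1 1, WT 1 or WT 3) and Gm8238 (without SOD1 1, WT 1 or WT 3), with adjusted p up to 0.233. Leaving out 1 library gave 5 without SOD1 1, SOD1 2, WT 1 or WT 2 and 3 without WT 3 at T0, 25 without SOD1 2, 4 without WT 2 and 2 without WT 3 at T2 and 7 without WT 1 or WT 3 at T20. In the fit of T2 libraries alone 0 genes were called by the edgeR test and at T0 1, while limma voom called 3, 28 and 15 genes at T0, T2 and T20 and DESeq2 11, 48 and 18. Without the libraries of low depth or few genes the counts were 3, 2 and 8, with Sod1 lost at T2 and T20 (adjusted p = 0.356 and 0.105). At T2 the nuclear genes of oxidative phosphorylation had a median of -0.54 (camera adjusted p = 1.88e-08, p = 0.899 with an estimated correlation), with Atp5b, a subunit of ATP synthase, at -0.95 ± 0.30 and Cox8a at -1.29 ± 0.41. None of the 26 passed (0 and 0 adjusted over the list alone), and the call was lost without SOD1 1 (adjusted p = 0.516). Beside them mitochondrially encoded transcripts had a median of -0.38 (camera adjusted p = 0.00659, p = 0.899 with an estimated correlation), lost without SOD1 1 or WT 1 (p up to 0.516), with 0 rising and 0 falling (0 and 1 adjusted over the list alone).

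Whether the genotypes responded differently to activation was tested as an interaction. The edgeR quasi-likelihood test called 0 genes for T2 against T0 (486 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma voom) and 0 for T20 against T0 (444 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom). Mitochondrially encoded transcripts had a median of -0.81 (camera adjusted p = 1.20e-04, p = 0.888 with an estimated correlation) for T2, lost without T2 SOD1 1 (adjusted p = 0.0900). Of these transcripts 0 rose and 0 fell (0 and 1 adjusted over the list alone). Without T2 SOD1 2, 1 gene was called. T20 against T2, a comparison added after the data were seen, gave 0 genes (457 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma voom), and 1 without T2 SOD1 2. There the nuclear genes of oxidative phosphorylation had a median of 0.25 (camera adjusted p = 3.64e-05, p = 0.866 with an estimated correlation), with 0 rising and 0 falling (0 and 0 adjusted over the list alone), a call lost without T2 SOD1 1 (adjusted p = 0.843). Mitochondrially encoded transcripts had a median of 0.32 (camera adjusted p = 0.00378, p = 0.798 with an estimated correlation), lost without T20 SOD1 1, T20 WT 1, T2 SOD1 1 or T2 WT 3 (p up to 0.275).

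Over 26 comparisons and 31 lists fixed before the data were examined, 750 list tests gave 152 calls with the preset correlation, and 11 of them held with an estimated one. These were tissue-restricted antigens and immediate early genes in cTEC of d30 between genotypes, the glucocorticoid and heat shock lists in cTEC by age, G2/M phase genes in CD4 cells by age and, at T2 and at T20, the Treg signature, immediate early genes and S phase genes. With that correlation all but G2/M phase genes lost their call without at least 1 library. 2 lists were called in no comparison, with a lowest camera adjusted p of 0.0504 for endothelial markers and 0.0780 for germinal centre and plasma cell markers. The labels do not say whether the libraries of a group came from separate animals, so each p measures only the spread between these libraries, which can be technical. Counts of all 68 pairs of libraries within groups differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.13.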

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

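The tests of signal that travels with the transgene, of Gm15772 in every animal, of exchanged labels and of a shared batch were chosen after the results were seen, and the others before. Gene lists stood out where the genotype difference itself differed between days or culture times by camera with the preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.241 to 0.888). In cTEC the median log2 difference between the genotype effects of d120 and d30 was 0.57 for TCR-induced immediate early genes, 0.71 for type I interferon response, 0.50 for MHC class II presentation, 0.23 for glucocorticoid response, 0.45 for heat shock and unfolded protein response, 0.28 for oxidative phosphorylation, 0.72 for mitochondrially encoded transcripts and 1.03 for inflammatory cytokines and chemokines. In sorted Treg cells it was -0.93 for mTEC markers, -0.68 for Treg signature, -0.39 for TCR-induced immediate early genes, -0.81 for MHC class II presentation, 0.33 for S phase genes, -0.28 for p53 targets and apoptosis, -0.23 for heat shock and unfolded protein response, -0.52 for mitochondrially encoded transcripts, -0.30 for cholesterol synthesis and -0.63 for inflammatory cytokines and chemokines. In CD4 cells it was -1.16 for T helper lineage genes, -0.86 for MHC class II presentation, 0.25 for G2/M phase genes, -0.46 for heat shock and unfolded protein response, -0.58 for oxidative phosphorylation, -0.55 for mitochondrially encoded transcripts and -1.30 for myeloid and dendritic cell markers, where the median for myeloid and dendritic cell markers was -1.43 with members at 0 on 1 side set at their bound. In the cultures the difference between the genotype effects of T2 and T0 was 1.24 for G2/M phase genes, -0.31 for oxidative phosphorylation and -0.81 for mitochondrially encoded transcripts. Of these calls, 4 in Treg cells (mTEC markers, MHC class II, S phase and inflammatory genes) were kept with each library left out, and every other one was lost without at least 1 library. In cTEC the immediate early, heat shock and mitochondrial lists were lost without d120 SOD1 3 (adjusted p up to 0.733) and the rest without 1 or more of d120 SOD1 1, d120 SOD1 2, d120 SOD1 3, d120 WT 1, d120 WT 2, d120 WT 3, d30 SOD1 1, d30 SOD1 2, d30 SOD1 3, d30 WT 2 or d30 WT 3 (adjusted p up to 0.976), class II and inflammatory genes in the other direction. In Treg cells they were lost without 1 or more of d120 SOD1 1, d120 SOD1 2, d120 SOD1 3, d120 WT 1, d120 WT 3, d30 SOD1 3, d30 WT 2 or d30 WT 3 (adjusted p up to 0.432). In CD4 cells they were lost without 1 or more of d120 SOD1 1, d120 SOD1 2, d120 SOD1 3, d120 WT 1, d120 WT 2, d30 SOD1 1, d30 WT 2 or d30 WT 3 (adjusted p up to 0.874), and in the cultures without T2 SOD1 1 and, for G2/M phase genes, 7 other libraries (adjusted p up to 0.786). Oxidative phosphorylation in both and G2/M phase genes in the cultures turned direction in 1 of these fits.

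Loci other than Sod1 were higher in SOD1 libraries, Gm8566 first among them. Sequence resemblance to Sod1 is a candidate explanation for Gm8566, whose transcript aligns to a Sod1 transcript over 465 bases, so that reads of the transgene may be counted there. Resemblance to the mouse Sod1 transcript cannot be the whole cause, since 1 of the 15 other loci, Gm8238, aligned to it over the minimum length of 50 bases. The sequence of the human transgene was not used here, so resemblance to it was not tested and stays open for these loci. Signal that travels with the transgene whatever the cell type stays open as a hypothesis, since 6 of the 9 loci of the cultures had every SOD1 whole thymus library above every WT one. A response of the cells to the mutant protein was not tested apart from it.

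Gm15772 was lower in the SOD1 cultures at all 3 times. That the transgene lowers Gm15772 in every animal is argued against by d120 SOD1 2 and SOD1 3, over 20 CPM in all 4 populations. SOD1 1 and WT 2 lay under 5 CPM in all 4, perhaps each as 1 animal. Background variants shared by the cultures of 1 genotype stay open, since of 8 other genes that are on or off by sorted library 2 were in 1 state in all libraries of each culture genotype and 5 were on and off within a genotype, too few to decide. What lowers Gm15772 in the SOD1 cultures stays open.

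The d120 Treg and CD4 libraries part by the numbers in their column names, across genotypes. Numbers 1 to 3 are SOD1 1, SOD1 2 and WT 1, and 4 to 6 SOD1 3, WT 2 and WT 3. An exchange of the labels of SOD1 3 and WT 1 is excluded, since the lowest Gm8566 level of SOD1 3 over the 4 populations was 47.5 CPM. A difference in depth is not the whole cause, since the split of Treg libraries still called 524 genes once each library was thinned to the smallest total, against 683 before. A batch shared by numbers 1 to 3 and by 4 to 6 may be the source. This split called 683, 293, 2 and 0 genes in Treg, CD4, mTEC and cTEC, and the highest other split 2, 1, 1 and 1.

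Other splits of the same libraries were counted for each comparison of groups of 3 or more. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real count against the highest of the other splits was 12 against 20 in whole thymus (2 of 10 splits), 3 against 3 in iLN (2 of 10 splits), 1 against 1 in cTEC d120 (2 of 10 splits), 1 against 0 in mTEC d30 (1 of 10 splits), 1 against 2 in mTEC d120 (3 of 10 splits), 2 against 0 in Treg d30 (1 of 10 splits), 2 against 683 in Treg d120 (2 of 10 splits), 1 against 293 in CD4 d120 (5 of 10 splits), 8 against 3 in cultures at T0 (1 of 10 splits), 11 against 0 in cultures at T2 (1 of 10 splits) and 11 against 0 in cultures at T20 (1 of 10 splits). In Treg and CD4 cells of d120 the split that called 683 and 293 genes is that of the numbers 1 to 3 against 4 to 6, which points to a structure of the samples. By age the real split ranked first of those drawn, the lowest share they can give, with age and batch not parted. It called 677 against 1 in cTEC (1 of 100 splits) and 597 against 1 in mTEC (1 of 40). In Treg it called 4433 against 3 (1 of 50), and in CD4 1321 against 2 (1 of 100). For culture time it was also first, with 6850 against 2336 at T2 and 6863 against 0 at T20 (1 of 25 each). The highest other split of T2 exchanged 1 library of each time. For comparisons that called 0 genes every split gives as many whatever the data, so these counts say nothing of chance, with 0 against 1 in mTEC genotype by age (40 of 40 splits), 0 against 35 in Treg genotype by age (50 of 50 splits), 0 against 2 in genotype by T2 (25 of 25 splits), 0 against 1 in genotype by T20 (25 of 25 splits) and 0 against 7 in T20 against T2 (25 of 25 splits). The splits of the Treg interaction reached 35 genes, which again points to a structure of the samples.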

How the results depend on the processing

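The fits with 1 dispersion for all genes, without libraries of low depth or few genes, without pile-up loci and with the set of d120 libraries as a covariate, the pseudocounts of whole thymus and the list tests with each library left out or with that set as a covariate were chosen after the data were seen. Counts of called genes within 1.5 times of the reported ones were not listed. Median-of-ratios scaling moved none of the counts by more than that, nor did leaving out the pile-up loci. Counts by DESeq2 were 5 for cTEC d30, 208 for cTEC d120, 1593 for cTEC d120 vs d30, 25 for cTEC genotype by age, 4 for mTEC d30, 87 for mTEC d120, 979 for mTEC d120 vs d30, 10 for mTEC genotype by age, 7 for Treg d30, 49 for Treg d120, 6 for Treg genotype by age, 5 for CD4 d30, 40 for CD4 d120, 2557 for CD4 d120 vs d30, 3 for CD4 genotype by age, 48 for cultures at T2, 18 for cultures at T20, 5 for genotype by T2, 1 for genotype by T20 and 3 for T20 against T2. Limma voom with sample quality weights gave 1 for iLN, 3 for cTEC d30, 0 for cTEC d120, 1919 for cTEC d120 vs d30, 2 for mTEC d30, 0 for mTEC d120, 1591 for mTEC d120 vs d30, 1 for Treg d120, 4 for CD4 d30, 0 for CD4 d120, 2788 for CD4 d120 vs d30, 3 for cultures at T0 and 28 for cultures at T2. Without the filter on low counts the test gave 40 for iLN, 52 for cTEC d30, 106 for cTEC d120, 1353 for cTEC d120 vs d30, 34 for cTEC genotype by age, 2 for mTEC d30, 98 for mTEC d120, 1256 for mTEC d120 vs d30, 14 for mTEC genotype by age, 90 for Treg d30, 222 for Treg d120, 140 for Treg genotype by age, 33 for CD4 d30, 105 for CD4 d120, 2096 for CD4 d120 vs d30, 28 for CD4 genotype by age, 91 for cultures at T0, 122 for cultures at T2, 64 for cultures at T20, 73 for genotype by T2, 58 for genotype by T20 and 43 for T20 against T2. Fits of the 2 groups alone gave 0 for cTEC d120, 5 for mTEC d30, 1 for Treg d120, 1 for cultures at T0 and 0 for cultures at T2. A dispersion shared by all genes gave 1319 for cTEC d120 vs d30, 2 for mTEC d30, 2 for mTEC d120, 1793 for mTEC d120 vs d30, 7 for Treg d120, 2425 for CD4 d120 vs d30 and 17 for cultures at T2. Leaving out the libraries of low depth or few genes gave 1 for iLN, 2 for cTEC d120, 1805 for cTEC d120 vs d30, 3 for cultures at T0 and 2 for cultures at T2. The set covariate gave 1171 for cTEC d120 vs d30, 1495 for mTEC d120 vs d30 and 2465 for CD4 d120 vs d30. The cause of these shifts was not tested.

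The replicate number as a block gave 1 for iLN, 0 for cTEC d30, 0 for cTEC d120, 203 for cTEC d120 vs d30, 333 for mTEC d120 vs d30 and 1 for Treg genotype by age, and it moved no other count by over 1.5 times. For culture time the block was each culture, by genotype and number, and its counts were among those not moved. Named genotype calls lost with the block were Mtmr7, Trav11 and Gm6741 in whole thymus, Sod1 (adjusted p = 0.464) and Gm10163 (adjusted p = 0.370) in iLN, Gm8566 in cTEC of d30 (adjusted p = 0.231) and d120 (adjusted p = 0.0913) and Olfr1193 in the cultures at T0 (edgeR quasi-likelihood test). In none of the comparisons did every pair of equal numbers have a correlation of deviations over 0.1, so the numbers were not taken to pair libraries. As a hint from the data, not the design, each culture library correlated best with its own number in 6 of 6 pairs for T2 against T0, 4 of 6 pairs for T20 against T0 and 6 of 6 pairs for T20 against T2, with correlations of up to 0.329. The column numbers of each culture run on over the 3 times, and no label says whether they mark 1 culture.

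With 1 library left out, the lowest and highest counts were 10 to 18 for whole thymus, 1 to 2 for iLN, 0 to 2 for cTEC d120, 80 to 1805 for cTEC d120 vs d30, 0 to 1 for cTEC genotype by age, 0 to 0 for cTEC d30, 1 to 79 for mTEC d120, 224 to 1049 for mTEC d120 vs d30, 0 to 5 for mTEC genotype by age, 1 to 1 for mTEC d30, 1 to 7 for Treg d120, 3485 to 4840 for Treg d120 vs d30, 0 to 1 for Treg genotype by age, 1 to 3 for Treg d30, 1 to 13 for CD4 d120, 156 to 1898 for CD4 d120 vs d30, 0 to 2 for CD4 genotype by age, 0 to 2 for CD4 d30, 3 to 6 for cultures at T0, 6381 to 7305 for T2 against T0, 6295 to 6928 for T20 against T0, 0 to 1 for genotype by T2, 0 to 0 for genotype by T20, 7 to 11 for cultures at T20, 0 to 1 for T20 against T2 and 2 to 25 for cultures at T2. Where that leaves a group with 1 or 2 libraries, its spread is taken from the other groups of the fit.

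Over all genes of the naming rule and all alternatives, 48824 of 51106 values kept their direction and side of the threshold, 799 lost a call, 492 gained one, and 991 changed sign among genes past the threshold in neither fit. Genes that were called never changed sign. Junb in cTEC d30, not called in any fit, ranged with 1 library left out from -0.87 without WT 2 to 0.21 without WT 3, with its sign reversed in the latter. Of 152 list calls, 11 held with an estimated correlation and 59 with fry, which turned the direction of 1, cholesterol synthesis in mTEC of d30. With each library left out in turn 69 of the 152 list calls were kept and 14 changed direction in at least 1 fit. With the set of d120 libraries as a covariate 70 of 86 list calls were kept and 0 changed direction, and the lost ones were 4 of 8 in cTEC genotype by age, 1 of 1 in mTEC d120, 6 of 12 in Treg d120, 1 of 10 in Treg genotype by age, 2 of 6 in CD4 d120 and 2 of 7 in CD4 genotype by age. DESeq2, limma voom and count-based fits were not run on whole thymus, whose values are TPM. On simulated data with 200 changed genes the share of 4-fold changes found was 0% in cTEC between genotypes and by age, 1% in mTEC and 1 to 4% in CD4 cells between genotypes, so a low count of called genes between these genotypes says little of other changes. It was 44 to 53% in sorted Treg cells, 42% in iLN, 38 to 45% in the cultures and 81% in whole thymus between genotypes, 31 to 75% by age in mTEC, Treg and CD4 cells and 77 to 81% by culture time, and of 2-fold changes at most 40% were found.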

Other observations

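The genes here were chosen after their values were seen. Plasma and CD8 cell genes were counted in sorts named for other cells. Jchain, the antibody joining chain, had group means of 1239 to 2194 CPM in cTEC and 276 to 1684 in Treg. Ighm, the IgM heavy chain, had means of 613 to 6342 CPM in cTEC. By library, immunoglobulin took 0.00575% (WT 3) to 8.89% (WT 2) of cTEC d120 counts. Cd8a had means of 203 to 308 CPM in libraries labelled CD4, beside 94.8 to 178 of Cd4. Whether these counts come from other cells was not tested.

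Genes of the Y chromosome fell in the cultures with activation. All 4 sex-linked genes tested were lower at T2 (4 of 4 adjusted over the list alone), with Ddx3y, an RNA helicase, at -1.79 ± 0.22, the demethylase genes Kdm5d at -1.73 ± 0.31 and Uty at -1.56 ± 0.44, and the translation factor gene Eif2s3y at -0.80 ± 0.25 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.47e-06 to 0.00993). The list had a median of -1.64 (camera adjusted p = 0.0449, p = 0.257 with an estimated correlation), a call lost with 7 of the 12 libraries left out in turn (adjusted p up to 0.0649). Ddx3y averaged 167 ± 32.1 and 186 ± 40.2 CPM at T0 in SOD1 and WT (n = 3 each).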
